A study of Danio rerio with 4 samples.

How the data were processed

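The series holds 4 RNA-seq libraries of Gata1+ cells sorted by flow cytometry from zebrafish embryos of a gata1:GFP line, 1 for each of control MO and foxo3b MO at 24 and 48 hpf. Per the labels, total RNA was extracted with TRIzol and libraries were made by a standard Illumina preparation. Reads were aligned with TopHat and quantified with Cufflinks on the Zv9 assembly, per the submitters' processing notes. Tool versions, options and the annotation are not given in the sources used here. Each file gives FPKM values deposited by the authors for 14417 genes with their loci, and identifiers were unique in each file. Totals of FPKM differ between libraries and were not rescaled in the main analysis.

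Current gene symbols were looked up for 14134 of the genes in a zebrafish gene table, used for names only, and genes are named by the symbol in the files. Loci are Zv9 coordinates as the files give them, and 1436 genes share a locus with others, up to 31 genes. Names turned into dates by spreadsheet software stood on 9 rows and were left as they were. Of the genes, 1548 were listed at 0 in at least 1 library; no fold is printed for these against a 0.

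Log2 folds were log2((FPKM + 1)/(FPKM + 1)) over the 11971 genes with a mean over the 4 libraries of at least 1 FPKM. The comparisons were foxo3b MO against control at 24 hpf and at 48 hpf, and 48 hpf against 24 hpf in control and in foxo3b MO, with the difference of the foxo3b MO log2 folds between stages. With 1 library per group no test was run. Genes were counted at a threshold of 2-fold. For the 33 gene lists (pathways, complexes, and markers of red cells and of other tissues), the median log2 fold was set against 10000 random lists of the same size, matched on mean expression in 20 bins. A list stood apart below percentile 2.5 or above 97.5, given at least 3 measured genes, and was called when its median was also at least 0.5 in size. Adult globins had too few measured genes for a percentile, leaving 32 lists. The percentile describes where a list lies among genes of these libraries and is not a p-value.

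Named genes followed a rule. It took foxo3b, the other FOXO genes, gata1a, klf1, tal1, alas2, slc4a1a, sptb, each globin, mdm2 and cdkn1a. It also took the 8 highest and 8 lowest log2 folds of each foxo3b MO comparison (5 for development, 6 for the difference between stages) among genes with a mean of at least 10 FPKM, a symbol, and a value above 0 in the libraries compared. In each list it took up to 4 members with the largest log2 fold and the most abundant member. Of the genes the rule takes, 2 are not reported here. A gene named under any comparison may have its value printed in the others. The comparisons, lists, thresholds, naming rule and the alternatives of the closing section, except the added centring described next, were fixed before the data were examined.

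Alternatives were pseudocounts of 0.1 and 5 FPKM, no floor, a floor of 5 FPKM, scaling by the median of ratios to the geometric mean over libraries, scaling to equal total FPKM with and without globins, and leaving out genes listed at 0. Globins took at most 1.34% of a library's total, so both equal-total scalings give nearly the same values and are not separate checks. Log2 folds centred within 10 bins of locus width and 5 bins of mean FPKM were added after the data were seen.

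Relative depth was estimated from genes below 0.3 FPKM, where a value of 1 read for a gene in each of 2 libraries fixes the ratio of their depths. The estimates rest on 652, 391 and 261 genes for foxo3b MO at 24 hpf, control at 48 hpf and foxo3b MO at 48 hpf, of which 65.2%, 66.5% and 64.4% lay within 0.03 log2 of a step, against medians of 20.1%, 15.9% and 19.2% at other offsets. These give ratios only, so no counting error is attached to any value.

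The steps were tested on simulated data made from the mean FPKM over the 4 libraries with noise of SD 0.3 log2. Past 2-fold, 0 of 50 genes shifted 1.5-fold were found, 15 of 50 shifted 2-fold, 44 of 50 shifted 3-fold and 50 of 50 shifted 4-fold, with 7 of 11771 unshifted genes. This noise was a chosen setting, alike at every expression level and without counting error. These numbers are therefore not rates of true or false calls in the 4 libraries. On the log2 folds measured at 24 hpf, 9 of 200 random lists stood apart, and 200 of 200 lists shifted 1.68-fold did. A simulated depth ratio of 0.55 was estimated as 0.551. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.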

Results

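RNA was sequenced from zebrafish embryos of a line that carries green fluorescent protein under the gata1 promoter, which is active in red blood cell precursors. Cells sorted as Gata1+ were collected at 24 and 48 hours post fertilization (hpf). Embryos had been injected with a standard morpholino oligonucleotide (MO), used as control, or with an MO against foxo3b, a gene for a FOXO transcription factor. There were 4 groups (control and foxo3b MO at each stage) with 1 library each, so there were no replicates. No spread within a group can be given, no test was run, and each value below is a description of these libraries. Values are FPKM as deposited by the authors, which are fragments scaled by transcript length and by mapped fragments, for 14417 genes.

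Total FPKM over these genes was 2288669 in control and 1576674 in foxo3b MO at 24 hpf, and 2402299 in control and 1505447 in foxo3b MO at 48 hpf. The files hold no counts, so absolute depth is unknown and no counting interval is given. Low FPKM values lie on steps set by single reads, and these steps gave a depth, relative to control at 24 hpf, of 0.543 for foxo3b MO at 24 hpf, 0.712 for control at 48 hpf and 0.497 for foxo3b MO at 48 hpf. Genes listed at 0 numbered 938, 1047, 748 and 1151 in the same order as the totals. Log2 folds were computed with 1 FPKM added to each value, over the 11971 genes with a mean of at least 1 FPKM.

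The libraries held abundant transcripts of tissues other than blood in every group. Ribosomal protein genes made up 54.2% of total FPKM in control and 43.7% in foxo3b MO at 24 hpf, and 43.5% and 30.7% at 48 hpf. With their most abundant gene, zgc:77235, left out of the sum but not of the total, the shares at 48 hpf were 30.7% and 27.6%. The control total still held this gene at 307548 FPKM, which lowers the control share, so these values overstate how close the shares were. The most abundant gene of both 24 hpf libraries was fabp1b.1, a fatty acid binding protein gene of yolk and gut, at 122922 FPKM in control and 88013 FPKM in foxo3b MO. The keratin gene krt4, an epidermal marker, stood between 8263 and 10879 FPKM in the 4 libraries. The hatching gland protease gene he1b stood at 4864 FPKM in control and 4627 FPKM in foxo3b MO at 24 hpf, and at 1334 and 2990 FPKM at 48 hpf. By comparison gata1a, the erythroid transcription factor gene behind the reporter, had 8.23 FPKM in control and 6.30 FPKM in foxo3b MO at 24 hpf, and 2.49 and 4.33 FPKM at 48 hpf. Embryonic and adult globin genes together took 0.761% of total FPKM in control and 0.260% in foxo3b MO at 24 hpf, and 1.34% and 0.811% at 48 hpf.

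The first comparison asks which transcripts differed between Gata1+ cells of foxo3b MO and control embryos at 24 hpf. Embryonic globin genes, which encode the oxygen carrier of the first red cells, were lower in the foxo3b MO library, with a median log2 fold of -1.97 over 7 measured genes. Genes of the damage response, which act in cell cycle arrest and cell death after DNA damage, were higher, with a median log2 fold of 1.2 over 19 genes, and the cyclin gene ccng1 stood at 2311 FPKM against 348 FPKM. Ribosomal protein genes were lower, with a median of -0.76 over 87 genes, and so were lens and eye markers, with a median of -0.71 over 18 genes. The directions of these 4 lists held on each of the scalings tried.

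The mRNA of foxo3b itself was higher, not lower, in the library labelled foxo3b MO: 46.5 FPKM against 6.40 FPKM at 24 hpf, a log2 fold of 2.68, and 50.3 FPKM against 38.1 FPKM at 48 hpf, a log2 fold of 0.39. The gene lies on chromosome 20 of the Zv9 assembly, at 32325663 to 32371617. The labels do not say where the MO binds, and a transcript level does not check an MO that blocks translation, so the extent of the knockdown is not known from these data. Of the other FOXO genes at 24 hpf, foxo3a stood at 10.7 FPKM against 8.90 FPKM, foxo1a at 4.38 FPKM against 2.56 FPKM and foxo1b at 1.83 FPKM against 0.839 FPKM. The FOXO family list of 5 measured genes had a median of 0.60 at 24 hpf, at percentile 96.1 of expression-matched random lists.

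At 24 hpf 373 genes were at least 2-fold higher and 232 at least 2-fold lower in foxo3b MO, and 94.9% of genes lay within 2-fold. This split depends on the scale, and the median log2 fold of all genes was 0.19 on the deposited scale. Rescaling by the median of gene ratios moved that median by -0.19 and gave 193 higher and 365 lower genes. Rescaling to equal totals moved it by 0.46 and gave 2319 higher and 82 lower, and equal totals without globins moved it by 0.45 and gave 2270 higher and 82 lower. Ribosomal protein genes, themselves a list compared here, weigh heavily on that scale. They summed to 1241330 FPKM of a total of 2288669 FPKM in control and to 688602 FPKM of 1576674 FPKM in foxo3b MO. With a pseudocount of 5 FPKM, 121 genes were higher and 142 lower. Rescaling moves genes nearly alike, so a list median that changes sign with it shows where 0 lies, not where the list lies among other genes.

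Of the 7 embryonic globin genes, 6 were at least 2-fold lower in foxo3b MO at 24 hpf, and the list median lay below those of all 10000 random lists. The largest difference was in hbbe3, an embryonic beta globin gene on chromosome 12, at 1815 FPKM against 9075 FPKM, a log2 fold of -2.32. The alpha globin gene hbae3 stood at 928 FPKM against 2485 FPKM, and hbbe2 at 56.5 FPKM against 172 FPKM. Similar values came from hbae1 (486 FPKM against 1907 FPKM), hbbe1.1 (359 against 1663) and LOC573653, now named hbbe1.3 (435 against 2080). These last genes share a locus of 5 genes on chromosome 3 in the files, so their single values are uncertain. The 4 embryonic globin genes at loci of their own had a median log2 fold of -1.50. The exception within the list was zgc:163057 (hbae4), at 14.3 FPKM against 22.7 FPKM. Of the adult globins only zgc:92880 (hbba2) passed the floor, at 2.5 FPKM against 4.56 FPKM.

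**Figure D1:**
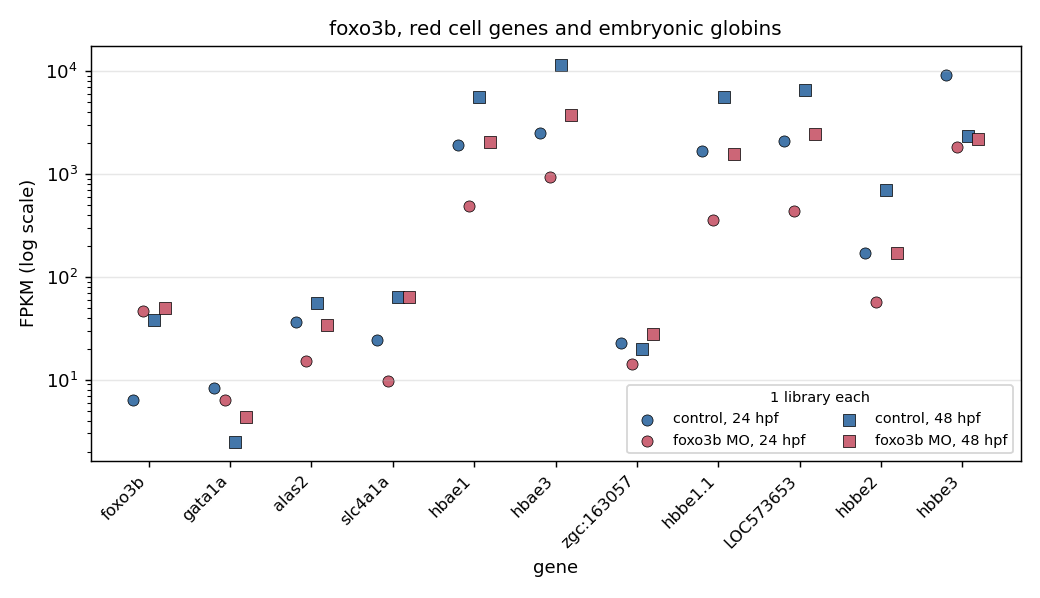
FPKM on a log axis for foxo3b, gata1a, alas2, slc4a1a and the embryonic globin genes in each of the 4 libraries, with 1 point per library. At 24 hpf the foxo3b MO points lie below control for the 7 globin genes, as for hbbe3 at 1815 against 9075 FPKM, a direction that held for the list median on each scaling tried; at 48 hpf hbbe3 lies at 2207 against 2340 FPKM.

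Lists of other red cell genes had medians closer to 0 than the globins at 24 hpf, though single genes such as tmem14c (log2 fold -1.77) differed as much as some globins. Heme synthesis genes had a median log2 fold of -0.36 over 13 genes and red cell membrane and cytoskeleton genes one of -0.28 over 12 genes, which equal totals turned to 0.15 and 0.21. Both lists stood apart below random lists, at percentiles 0.01 and 0.06. In each list 2 genes were at least 2-fold lower and none 2-fold higher. The erythroid heme synthesis gene alas2 stood at 15.2 FPKM against 36.8 FPKM, and tmem14c, which carries a heme precursor into mitochondria, at 93.5 FPKM against 321 FPKM. The anion exchanger gene slc4a1a, the main red cell membrane transporter, stood at 9.66 FPKM against 24.1 FPKM and the blood group gene rhd at 3.54 FPKM against 8.46 FPKM. The spectrin gene sptb differed less, at 16.8 FPKM against 19.2 FPKM. Among transcription factor genes, tal1 stood at 14.6 FPKM against 15.5 FPKM and klfd, now named klf1, at 1.35 FPKM in both. The 15 erythroid transcription factor genes had a median of 0.06 (percentile 8.01), which the median-ratio scaling turned negative, the 13 blood progenitor genes 0.27 (percentile 70.5), and the 11 iron uptake and storage genes 0.26 (percentile 75.3).

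In the damage response list 10 of 19 measured genes were at least 2-fold higher and none 2-fold lower at 24 hpf, and the list median lay above those of all 10000 random lists. The ubiquitin ligase gene mdm2, which DNA damage induces, stood at 159 FPKM against 28.6 FPKM. Among genes of cell death, casp8 stood at 56.4 FPKM against 4.56 FPKM, phlda3 at 63.5 FPKM against 6.94 FPKM and bbc3 at 7.77 FPKM against 1.2 FPKM. The DNA damage gene gadd45aa stood at 20.4 FPKM against 3.93 FPKM. The death gene pmaip1 stood at 285 FPKM in foxo3b MO at 24 hpf and was listed at 0 in the other libraries. The cell cycle inhibitor gene cdkn1a was not analysed here. Genes known as FOXO targets, 6 of which are also in the damage response list (bbc3, gadd45aa, gadd45ab, sesn1, pmaip1 and ccng2), had a median of 0.31 over 32 genes, at percentile 88.0 of random lists. Of these, 7 were at least 2-fold higher and none 2-fold lower. They included sesn3, a stress response gene outside the damage response list, at 49.9 FPKM against 15.7 FPKM.

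**Figure D2:**
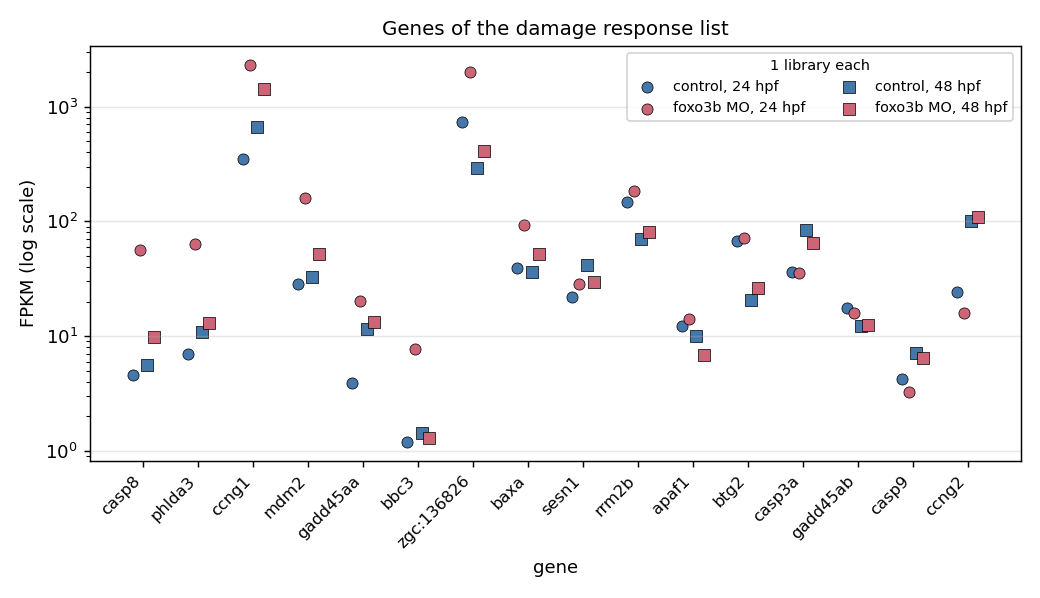
FPKM on a log axis for 16 genes of the damage response list, each above 0 in every library, in each of the 4 libraries, with 1 point per library. The foxo3b MO library at 24 hpf holds the highest value for mdm2 (159 FPKM) and ccng1 (2311 FPKM), and the higher median of the damage response list at 24 hpf held on each scaling tried.

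Ribosomal protein genes, one of the longest lists, held the most 2-fold lower genes of any list at 24 hpf, though a smaller share than the globins (6 of 7). In the ribosomal protein list 33 of 87 genes were at least 2-fold lower and 2 were 2-fold higher, below all 10000 random lists, with rplp2l, a ribosomal stalk protein gene, at 10232 FPKM against 40398 FPKM. Of 90 genes of oxidative phosphorylation 19 were 2-fold lower, with a median of -0.35 (percentile 0) that equal totals turned to 0.19. The gene cox6c, for a subunit of cytochrome oxidase, stood at 736 FPKM against 2865 FPKM. The 66 mitochondrial ribosomal protein genes had a median of -0.15 (percentile 0.01), which equal totals turned to 0.38.

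Heat shock and immediate early genes had a median of 0.18 (percentile 72.4, negative with median-ratio scaling) and unfolded protein response genes 0.04 (percentile 24.8, negative on the same scaling), with no heat shock gene 2-fold higher. Antioxidant enzyme genes, at -0.19 (percentile 0.93), and autophagy genes, at 0.00 (percentile 1.83), stood apart below random lists, but equal totals turned the antioxidant median to 0.29 and median-ratio scaling the autophagy median to -0.22. In these lists prdx3, a mitochondrial peroxidase gene, stood at 91.1 FPKM against 159 FPKM, sod1, a superoxide dismutase gene, at 58.6 FPKM against 102 FPKM, and atg12 at 32.8 FPKM against 66.5 FPKM. Glycolysis genes had a median of -0.14 (percentile 2.56), which equal totals turned to 0.29, and within it pklr, the pyruvate kinase gene of red cells and liver, stood at 16.6 FPKM against 78.2 FPKM. Hypoxia response genes had a median of 0.37 (percentile 89.6), with vegfaa, a vascular growth factor gene, at 17.8 FPKM against 6.48 FPKM. Interferon response genes had a median of 0.41 (percentile 88.4), with isg15, an interferon-induced ubiquitin-like modifier, at 25.2 FPKM against 1.28 FPKM. Proteasome genes (0.08, percentile 88.5) and cell cycle genes (0.03, percentile 26.0) did not stand apart from random lists, and both medians turned negative with median-ratio scaling.

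Among markers of other tissues at 24 hpf, the lens gene cryba4 stood at 38.8 FPKM against 98.3 FPKM and 5 of 18 lens and eye markers were 2-fold lower. The median of this list fell below 0.5 in size with a pseudocount of 5 FPKM (-0.33) and with no floor (-0.39). Liver and yolk markers stood apart below random lists (percentile 0), with a median of -0.49 over 25 genes, which equal totals turned to 0.01. The vitamin A carrier gene rbp4 stood at 181 FPKM against 695 FPKM. Neural (-0.23) and pigment cell (-0.28) markers, which equal totals put at 0.28 and 0.21, stood apart below random lists, at percentiles 0.03 and 0.24. Epidermis markers (0.24) and notochord and cartilage markers (0.39) were higher than random lists, at percentiles 99.9 and 98.6, and their medians stayed positive on each scaling tried. Muscle markers had a median of -0.25 (percentile 31.5, positive with equal totals), with pvalb2, a muscle calcium-binding protein gene, at 281 FPKM against 1112 FPKM. Endothelial (0.32, percentile 77.2) and thrombocyte markers (0.20, percentile 45.2) lay inside the range of random lists, and so did myeloid (0.11, percentile 13.1) and hatching gland markers (0.12, percentile 83.8), both of which median-ratio scaling turned negative. The myeloid lysozyme gene lyz stood at 5.75 FPKM against 33.3 FPKM.

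The highest log2 fold at 24 hpf among genes with a symbol that is not a clone or database name, a mean of at least 10 FPKM and values above 0 in both libraries was that of vgll4, a gene for a transcription cofactor, at 2565 FPKM against 18.1 FPKM. Next came mcoln1, a lysosomal ion channel gene (114 FPKM against 8.01 FPKM), followed by isg15, fgf2, casp8, phlda3, lnx1 and mir363. The growth factor gene fgf2 stood at 339 FPKM against 30.5 FPKM, and its row spans a locus shared by 15 genes, so that value is uncertain. Among the 8 lowest of these genes were lyz, hbbe3, hbbe1.1, pklr, hbl4, dap1b and pvalb2. The row of dap1b spans a locus shared by 3 genes, so its value is uncertain.

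**Figure D3:**
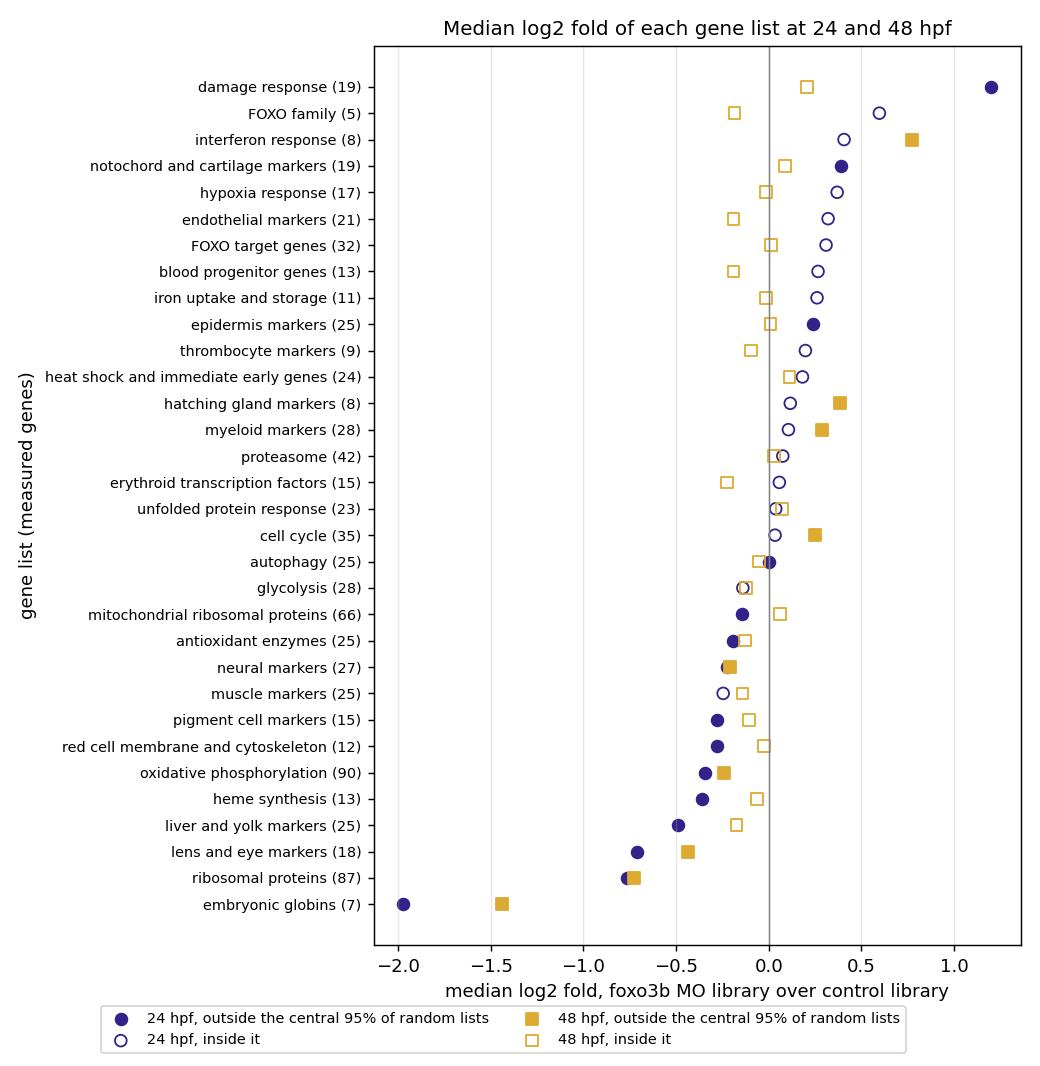
Median log2 fold, foxo3b MO against control, of each gene list with a percentile at 24 hpf and at 48 hpf, with 1 FPKM added to each value. Embryonic globins (-1.97 and -1.44) lie lowest at both stages and damage response genes at 24 hpf (1.2) highest, signs that held on each scaling tried.

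At 48 hpf the same question was asked of the later stage. Embryonic globin genes were again lower in foxo3b MO, with a median log2 fold of -1.44, and 5 of 7 were at least 2-fold lower. The beta globin gene hbbe2 stood at 170 FPKM against 697 FPKM and the alpha globin gene hbae3 at 3710 FPKM against 11506 FPKM, while hbbe3 stood at 2207 FPKM against 2340 FPKM. Ribosomal protein genes were lower, with a median of -0.73 over 87 genes and 17 at least 2-fold lower. Interferon response genes were higher, with a median of 0.78 over 8 genes, and 3 were at least 2-fold higher.

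The globin median at 48 hpf lay at percentile 0.02 of random lists and the ribosomal median below all 10000, and neither direction turned on another scale, although with equal totals they came to -0.76 and -0.05. The 4 embryonic globin genes at loci of their own had a median of -0.86, closer to 0 than at 24 hpf. In the shared chromosome 3 locus hbae1 stood at 2062 FPKM against 5589 FPKM, hbbe1.1 at 1564 against 5585 and LOC573653 at 2464 against 6508, while zgc:163057 on chromosome 12 stood at 27.9 against 20.1. The adult gene zgc:92880 stood at 0.529 FPKM in control and was listed at 0 in foxo3b MO. At this stage slc4a1a stood at 63.4 FPKM against 63.2 FPKM, sptb at 21.6 FPKM against 22.5 FPKM and alas2 at 33.7 FPKM against 56.0 FPKM. Heme synthesis genes (-0.06, percentile 25.5) and red cell membrane genes (-0.03, percentile 33.3) did not stand apart, and both medians turned positive with equal totals. The rhesus transporter gene rhag, in the second list, stood at 77.9 FPKM against 139 FPKM. Transcription factor genes tal1 and klfd stood at 10.4 FPKM against 13.1 FPKM and at 5.80 FPKM against 5.03 FPKM.

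At 48 hpf 230 genes were at least 2-fold higher and 439 at least 2-fold lower, with an all-gene median log2 fold of -0.02. Equal totals moved that median by 0.61 and gave 2001 higher and 127 lower genes, and equal totals without globins gave 1951 and 129. Median-ratio scaling moved it by 0.02.

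In the interferon list at 48 hpf isg15 stood at 21.6 FPKM against 0.997 FPKM, irf1b at 3.97 FPKM against 0.565 FPKM and irf7, a transcription factor gene of the antiviral response, at 5.79 FPKM against 2.38 FPKM. Most of this list is weakly expressed, and a floor of 5 FPKM turned its median to -0.042, while a pseudocount of 5 FPKM gave 0.36 and no floor 0.39. Myeloid markers, of white blood cells, had a median of 0.29 over 28 genes (percentile 99.9), with 4 genes 2-fold higher and 1 lower. The inflammatory cytokine gene il1b stood at 10.9 FPKM against 1.43 FPKM, and the matrix protease genes mmp9 and mmp13a at 44.3 FPKM against 5.86 FPKM and 27.3 FPKM against 5.37 FPKM. The protease gene ctssb.1 stood at 115 FPKM against 21.1 FPKM. The lower gene was LOC100151049 (laptm5), a lysosomal membrane protein gene of blood cells, at 44.6 FPKM against 255 FPKM.

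The damage response list had a median of 0.21 at 48 hpf (percentile 95.7), inside the range of random lists. In it 2 genes were at least 2-fold higher, among them ccng1, at 1433 FPKM against 666 FPKM, while mdm2 stood at 52.2 FPKM against 32.5 FPKM. FOXO targets had a median of 0.01 (percentile 57.0). The FOXO family lay at -0.18 (percentile 31.4, positive with equal totals), with foxo1a at 11.1 FPKM against 6.03 FPKM and foxo1b at 1.3 FPKM against 3.97 FPKM.

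Cell cycle genes had a median of 0.25 at 48 hpf, at percentile 99.4 of random lists, and positive on each scaling tried. The replication genes rrm2, whose row shares a locus with others, and pcna stood at 376 FPKM against 179 FPKM and 812 FPKM against 521 FPKM. Hatching gland markers lay at 0.38 (percentile 98.9), also positive on each scaling, with 3 of 8 genes 2-fold higher: he1a at 1655 FPKM against 610 FPKM, he1b at 2990 FPKM against 1334 FPKM and ctsl1b at 143 FPKM against 55.1 FPKM. Oxidative phosphorylation genes lay at -0.24 (percentile 0.08), neural markers at -0.21 (percentile 0.52) and lens and eye markers at -0.44 (percentile 0.11). With equal totals these medians turned positive, to 0.43, 0.46 and 0.21. The crystallin genes crygm2d15 and crygm2d16, at 42.2 FPKM against 313 FPKM and 72.6 FPKM against 363 FPKM, share a locus of 25 genes on chromosome 9 and are uncertain as single genes.

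The remaining lists lay inside the range of random lists at 48 hpf. Medians that stayed positive on each scaling were those of heat shock and immediate early genes (0.11), the unfolded protein response (0.07), mitochondrial ribosomal proteins (0.06), the proteasome (0.03), epidermis (0.01) and notochord and cartilage (0.09). Medians below 0 that turned positive with equal totals were those of iron uptake and storage (-0.02), erythroid transcription factors (-0.22), blood progenitor genes (-0.19), autophagy (-0.05), antioxidant enzymes (-0.13), glycolysis (-0.12) and the hypoxia response (-0.01). The same held for muscle (-0.14), endothelial (-0.19), thrombocyte (-0.10), liver and yolk (-0.17) and pigment cell markers (-0.10). In these lists bnip3, a mitophagy receptor gene, stood at 0.384 FPKM against 5.11 FPKM, gpx4a, a lipid peroxidase gene, at 421 FPKM against 869 FPKM, and fabp1b.1 at 39376 FPKM against 187400 FPKM.

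Within the same limits on symbol, mean and values above 0, the highest log2 folds at 48 hpf were those of rn7sk, the RNA of a transcription elongation control complex, at 13681 FPKM against 667 FPKM, and rpph1, the RNA of ribonuclease P, at 1675 FPKM against 127 FPKM. They were followed by isg15, mmp9, ctssb.1, mcoln1 (117 FPKM against 25 FPKM) and mmp13a. The lowest of these genes was mkxb, a homeobox gene on an unplaced scaffold, at 1.62 FPKM against 296 FPKM, followed by adcyap1r1a (7.0 FPKM against 103 FPKM), crygm2d15, rpl37, the insulin gene ins (10.7 FPKM against 62.7 FPKM), crcp, plgrkt and crygm2d16.

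The stages can be set against each other because both hold the same contrast and share no library. Damage response genes differed between the stages: their median difference, log2 fold at 48 hpf minus log2 fold at 24 hpf, was -0.95, below all 10000 random lists. Notochord and cartilage markers had a difference of -0.54 (percentile 0.31) and the FOXO family one of -1.15 (percentile 0.51), and foxo3b itself one of -2.29. Globins had a difference of 0.53 (percentile 96.3), inside the range of random lists, with hbbe3 at 2.24. These signs held on each scaling tried, but the FOXO family difference came to -0.47 with a pseudocount of 5 FPKM and -0.43 with a floor of 5 FPKM. The notochord and cartilage difference came to -0.41 and -0.42 under these settings, and to -0.18 after centring by locus width and level, which was added after the data were seen.

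Smaller differences between stages that stood apart from random lists were those of heme synthesis (0.40), cell cycle (0.22), mitochondrial ribosomal protein (0.20), myeloid (0.39), epidermis (-0.30) and pigment cell genes (0.28). Within the limits on symbol and mean, the largest single-gene differences among genes with values above 0 in every library were -8.79 for mkxb, -6.18 for vgll4 and -4.45 for fgf2 at one end, and 4.29 for rpph1, 3.68 for hist1h4l, a histone gene, and 3.40 for mmp9 at the other. The median of this difference over all genes moved by 0.21 with median-ratio scaling and by 0.14 with equal totals.

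Of the genes at least 2-fold lower at 24 hpf, 50 were also 2-fold lower at 48 hpf, where 8.51 would be shared if the lists were independent, and 19 genes were higher at both stages, where 7.17 would be shared. Genes 2-fold higher at 24 hpf and lower at 48 hpf numbered 17 (13.7 if independent), and those lower and then higher 15 (4.46). Across genes, which are not independent replicates, the log2 folds of the stages had a Pearson r of 0.14 and a Spearman rho of 0.14.

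The third comparison sets 48 hpf against 24 hpf in control. Embryonic globins had a median log2 fold of 1.65, with 5 of 7 genes higher at 48 hpf. The others were hbbe3, at 2340 FPKM at 48 hpf against 9075 FPKM at 24 hpf, and zgc:163057, at 20.1 FPKM against 22.7 FPKM. Heme synthesis genes were lower, with a median of -1.01, and 7 of 13 were at least 2-fold lower. Cell cycle genes were lower, with a median of -0.91 and 16 of 35 at least 2-fold lower. Glycolysis genes were higher, with a median of 1.16 and 16 of 28 at least 2-fold higher. These directions held on each scaling tried.

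Among red cell genes, rhag stood at 139 FPKM at 48 hpf against 16.2 FPKM at 24 hpf and cahz, the red cell carbonic anhydrase gene, at 223 FPKM against 46.7 FPKM, and the red cell membrane list had a median of 0.77. The heme synthesis genes cpox and urod stood at 9.14 FPKM against 53.1 FPKM and 37.6 FPKM against 132 FPKM. The replication licensing genes mcm4 and gmnn stood at 20.5 FPKM against 101 FPKM and 18.7 FPKM against 78.0 FPKM. The pyruvate kinase gene pkm2b stood at 406 FPKM against 7.39 FPKM and the lactate dehydrogenase gene ldha at 274 FPKM against 38.7 FPKM. FOXO targets had a median of 0.72 (0.44 with a pseudocount of 5 FPKM and 0.45 after centring), with 11 genes 2-fold higher and none lower; among them sod2, a mitochondrial superoxide dismutase gene, stood at 77.9 FPKM against 5.25 FPKM and cat, the catalase gene, at 33.9 FPKM against 4.26 FPKM. Control foxo3b stood at 38.1 FPKM against 6.40 FPKM. Ribosomal protein genes had a median of -0.63 (-0.498 after centring).

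Markers of 5 other tissues were also higher in the control library at 48 hpf, on each scaling tried: lens and eye (3.87), muscle (1.62), pigment cell (1.36), neural (1.1) and liver and yolk (0.61, or 0.45 with a pseudocount of 5 FPKM and 0.43 with no floor). Endothelial markers stood apart below random lists, at -0.26 (percentile 0.845). Epidermis (-0.17), hatching gland (-0.07), notochord and cartilage (0.39), myeloid (0.35) and thrombocyte markers (0.04) did not stand apart, and the thrombocyte median turned negative on the other scalings. The muscle gene pvalb2 stood at 15493 FPKM against 1112 FPKM, the neural gene stmn1b at 726 FPKM against 60.1 FPKM and the pigment gene tyrp1b at 266 FPKM against 26.5 FPKM. Within the limits on symbol, mean and values above 0, the 5 highest genes were crystallins of the shared chromosome 9 locus, up to a log2 fold of 8.79 for crygm2d10. The 5 lowest within them were he2, ctsll, ctsl1b, ednrab and irg1l, of which he2 is a hatching enzyme gene, at 1.22 FPKM against 205 FPKM. The row of ednrab spans a locus shared by 9 genes, so its value is uncertain. In all 2509 genes were at least 2-fold higher and 1047 lower (70.6% of these higher). Median-ratio scaling moved the all-gene median of 0.18 by -0.19 and gave 2107 and 1457 (59.1% higher).

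In foxo3b MO the same stages showed much of the same course. Embryonic globins were higher at 48 hpf, with a median log2 fold of 2.0, and red cell membrane genes had a median of 1.05, glycolysis genes one of 1.25 and cell cycle genes one of -0.76. Lens and eye (4.66), muscle (1.94), pigment cell (1.40) and neural markers (1.21) were higher, and ribosomal protein genes lower (-0.62). Damage response genes were lower at 48 hpf than at 24 hpf, with a median of -0.95 and 9 of 19 genes at least 2-fold lower, where the control median was 0.18. FOXO targets, at 0.72 in control, had a median of 0.07 in foxo3b MO (percentile 74.7), with 8 genes 2-fold higher and 5 lower. Heme synthesis genes, at -1.01 in control, lay at -0.61 in foxo3b MO (percentile 2.74). Neither list stood apart from random lists in foxo3b MO. Epidermis (-0.48), hatching gland (-0.21), notochord and cartilage (-0.10), thrombocyte (0.05) and liver and yolk markers (0.33) did not stand apart from random lists. The directions in foxo3b MO held on each scaling tried.

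Myeloid markers had a median of 1.1 in foxo3b MO and 0.35 in control, and endothelial markers one of -0.67 and -0.26, also with the same signs on each scaling. The endothelial median in foxo3b MO came to -0.35 with a pseudocount of 5 FPKM. The myeloid gene lyz stood at 214 FPKM at 48 hpf against 5.75 FPKM at 24 hpf in foxo3b MO. The globin gene hbbe3 stood at 2207 FPKM against 1815 FPKM, and foxo3b at 50.3 FPKM against 46.5 FPKM. Within the same limits the lowest genes were vgll4, he2, uox, cyp11a1 and cyp4t8, and the highest included crygm2d10 and the adenine nucleotide carrier gene slc25a4, at 708 FPKM against 1.37 FPKM. In all 1882 genes were 2-fold higher and 1376 lower (57.8% higher). Of the genes 2-fold higher in control, 1464 were also 2-fold higher in foxo3b MO (394 if independent), and 673 were lower in both (120 if independent). Only 15 genes were higher in control and lower in foxo3b MO, and 9 the reverse. Across genes the developmental log2 folds of both arms had a Pearson r of 0.80 and a Spearman rho of 0.786.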

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

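The tests of explanations in this part were all chosen after the results were seen, and no explanation in it was tested on other data.

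Among the named genes with values above 0 in all 4 libraries, 5 were at least 2-fold higher in foxo3b MO at one stage and at least 2-fold lower at the other, which is what drew attention to them; the difference was not tested, and each value rests on 1 library. The difference, log2 fold at 48 hpf minus log2 fold at 24 hpf, was -8.788 for mkxb (1.96 at 24 hpf and -6.83 at 48 hpf), -4.449 for fgf2 (3.43 and -1.01) and -4.007 for lsamp (2.70 and -1.31). It was 3.683 for hist1h4l (-1.96 and 1.72) and 2.266 for mustn1 (-1.12 and 1.15). Over 7052 genes looked at, 20 were opposite and 52 in the same direction past 2-fold at both stages.

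Embryonic globins were lower in foxo3b MO at both stages. At 24 hpf the globin median lay at percentile 0 of random lists drawn from 61 abundant genes at loci of their own of at most 1500 bp. This argues against a shift of genes at such narrow loci. Locus width is not transcript length, and ribosomal protein genes, also abundant, had a median of -0.76. A shift of short abundant transcripts is therefore not excluded. Removing the linear trend with development left the globin median at -1.99 (-1.18 at 48 hpf, at percentile 0.05). The slope of that trend, -0.09 at 24 hpf and -0.14 at 48 hpf, was too shallow to remove a difference of this size. This step therefore cannot decide whether a developmental delay contributes. Other red cell genes, 9 with a mean of at least 10 FPKM, had a median of -0.35 at 24 hpf, with a 25th percentile of -1.23. At 48 hpf their median was -0.36, with a 25th percentile of -0.51. As a set they were lowered less than the globins, although pklr at 24 hpf (-2.17) lay below the globin median. This cannot exclude fewer red blood cells as the cause, since the libraries held abundant transcripts of other tissues, where such genes may also be expressed. The 4 embryonic globin genes at loci of their own were also lowered less, with medians of -1.50 at 24 hpf and -0.86 at 48 hpf. At 48 hpf a shift of genes at narrow loci stays open as well, since the globin median lies at percentile 3.96, inside the central 95%. A smaller share of red cells in the libraries, despite the Gata1+ sort, may still contribute at 24 hpf, where heme synthesis and red cell membrane lists stood apart at percentiles 0.01 and 0.06, and so may an effect of foxo3b, which was not tested apart from the MO.

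Damage response genes were higher in foxo3b MO at 24 hpf. A stress response through heat shock and immediate early genes is argued against by their list, at percentile 72.38, with 0 of 24 genes 2-fold higher. The unfolded protein response list lay at percentile 24.8, with 1 of 23 genes, asns, 2-fold higher. Other kinds of stress response were not tested. A trend with locus width and abundance is argued against too, since the damage response median after centring was 1.17, above all random lists. Morpholinos can turn on such genes by themselves, and activation of damage response genes by the morpholino apart from foxo3b cannot be told apart from an effect of foxo3b, because 0 libraries used another foxo3b reagent. Loss of foxo3b stays open as the biological explanation, untested.

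Several RNAs without a poly(A) tail, first seen for rn7sk, rpph1 and hist1h4l, were higher in foxo3b MO at 48 hpf, but not hist2h2l (log2 fold -0.21), nor past 2-fold histh1l (0.20). More RNA without a poly(A) tail carried into the library may account for it: 6 such RNAs, without the genes that drew attention and a gene listed at 0, had a median log2 fold of 2.54, with 4 at least 2-fold higher, where 11 replacement histones, whose mRNAs have tails, had a median of -0.07. Examples outside the naming rule are the ribosomal RNA gene zgc:158463, at 32584 FPKM against 4223 FPKM, and the histone gene zgc:173652, at 67.0 FPKM against 3.2 FPKM. Cell cycle genes were higher by less as a set, with a median of 0.25 and a 75th percentile of 0.41, below the 25th percentile of these RNAs at 0.69. That 25th percentile rests on 6 values, of which hist2h2l and histh1l lay below 0.41. The cell cycle list also stood above random lists, at percentile 99.4. This step therefore cannot exclude more dividing cells. Of the replacement histones, h2afv was past 2-fold higher at 48 hpf, at 29.7 FPKM against 11.1 FPKM. At 24 hpf the RNAs without a tail did not move together in foxo3b MO: rn7sk was higher (log2 fold 1.65), while hist1h4l (-1.96) and zgc:173652 (-1.87) were lower. A change of the RNAs without a tail in the cells stays open, and the labels do not say whether libraries were selected for poly(A) RNA.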

How the results depend on the processing

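The alternative that centres log2 folds by locus width and level was chosen after the results were seen; the others were planned. Each value below is given against the main value, and the cause was not tested except where a higher pseudocount or floor, which shrinks or removes weakly expressed genes, moves a result by construction.

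Genes 2-fold higher at 24 hpf numbered 373 in the main analysis, and 778 with a pseudocount of 0.1 FPKM, 121 with 5 FPKM, 193 with median-ratio scaling, 2270 and 2319 with equal totals without and with globins, and 177 after centring. Genes lower numbered 232, and 393, 142, 365, 82 and 82 under the first 5 of these. At 48 hpf 230 genes were higher, and 368 and 97 with the smaller and larger pseudocount and 1951 and 2001 with equal totals. Genes lower numbered 439, and 196 with the larger pseudocount, 259 with a floor of 5 FPKM and 129 and 127 with equal totals. From 24 to 48 hpf in control 2509 genes were higher, and 1343 with the larger pseudocount and 1634 with the higher floor; 1047 were lower, and 643 with the larger pseudocount. In foxo3b MO the larger pseudocount gave 1004 higher in place of 1882 and 768 lower in place of 1376.

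With a floor of 5 FPKM the interferon median at 48 hpf turned from 0.78 to -0.042, and came to -0.22 for development in foxo3b MO and -0.65 for the difference between stages, while the thrombocyte median in control development came to 0.87. Lens and eye medians came to 3.28 in control and 3.52 in foxo3b MO development with the larger pseudocount, and to 2.61 and 1.96 with no floor. The pigment cell median in control development came to 0.73 with the larger pseudocount. The FOXO family median in control development came to 2.11 and 0.62 with the smaller and larger pseudocount and 0.82 after centring. Its difference between stages came to -1.89, -0.47 and, with the higher floor, -0.43.

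Of 306 values of 34 called list medians under alternatives, 297 changed by less than 1.5-fold, 8 changed by more with the sign kept, and 1 changed sign. Most of these 8 were smaller in size than the main value. Of these values 16, for 8 list medians, were below the limit of 0.5 in size that a call needs. Of 5891 values of 664 named log2 folds, 5451 changed by less than 1.5-fold and 440 by more. A reversal was counted only where the main log2 fold was at least 1 in size, and 0 such values changed sign. Smaller log2 folds can change sign with a scaling, and those changes were not counted. Pearson r stayed between 0.108 and 0.179 for the foxo3b MO folds and between 0.784 and 0.815 for development. List medians under a scaling are compared relative to the shift of all genes. Summing or leaving out repeated symbols did not apply, because identifiers were unique, and leaving out a library was not possible with 1 per group. Depth limits weakly expressed genes most in foxo3b MO at 48 hpf, which had the lowest relative depth, 0.497.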

Other observations

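The values in this part were looked up after the results were seen, no explanation is offered, and no test was run. Genes that differed 2-fold with development in both arms were set against the foxo3b MO log2 folds. The 1464 genes higher at 48 hpf in both arms had a median foxo3b MO log2 fold of -0.02 at 24 hpf and -0.24 at 48 hpf. The 673 genes lower at 48 hpf in both arms had medians of 0.24 and 0.26. The medians of all genes were 0.19 at 24 hpf and -0.02 at 48 hpf, so these genes lay close to all genes at 24 hpf. Over all 11971 genes the slope of the foxo3b MO log2 fold on the mean developmental log2 fold was -0.09 at 24 hpf and -0.14 at 48 hpf. Among the lowest genes of control development, ctsll stood at 18.4 FPKM in foxo3b MO against 5.05 FPKM in control at 48 hpf, irg1l at 30.9 FPKM against 6.59 FPKM and he2 at 5.30 FPKM against 1.22 FPKM. Equal totals moved the median of all genes at 48 hpf by 0.61, more than the size of these medians.

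Shares of total FPKM differed by tissue list between the libraries. A share also depends on the total, which was lower in foxo3b MO at both stages, so a higher share need not mean more FPKM. Liver and yolk markers took 6.48% in control and 6.76% in foxo3b MO at 24 hpf, and 8.91% and 3.98% at 48 hpf. The gene fabp1b.1 carried most of this. With it left out of the sum but not of the total, the shares were 1.11% and 1.18% at 24 hpf, and 1.11% and 1.37% at 48 hpf. The lower share in foxo3b MO at 48 hpf is therefore that of 1 gene. Muscle markers took 0.697% and 0.822% at 24 hpf and 2.92% and 3.91% at 48 hpf, though their summed FPKM was lower in foxo3b MO. It was 12968 FPKM against 15950 FPKM in control at 24 hpf and 58894 FPKM against 70043 FPKM at 48 hpf. Epidermis markers took 1.29% and 2.11% at 24 hpf and 1.81% and 2.19% at 48 hpf, and hatching gland markers 0.355% and 0.569%, then 0.112% and 0.363%. Summed FPKM of epidermis markers in foxo3b MO was 33336.5 FPKM against 29593 FPKM in control at 24 hpf, and 32972 FPKM against 43547 FPKM at 48 hpf. That of hatching gland markers was higher in foxo3b MO at both stages. The 10 most abundant genes took 24.5% and 23.2% of total FPKM at 24 hpf and 37.4% and 23.4% at 48 hpf. In control at 48 hpf the most abundant gene was zgc:77235 (rpl27a), at 307548 FPKM against 47268 FPKM in foxo3b MO.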
